A study of Pimephales promelas with 8 samples.

How the data were processed

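Total RNA from the ovaries of 8 adult female fathead minnows was measured, 4 controls and 4 exposed to a nominal 1 µg/L of 17β-trenbolone for 4 days. Per the labels' protocols, a lower concentration of 0.1 µg/L was part of the study but was not put on arrays, each treatment had 12 females spread over replicate tanks, and the ovary samples with the highest RNA integrity in each group were hybridised. Which fish came from which tank is not given in the sources used here. The labels number the controls 1, 3, 4 and 6 and the exposed fish 2, 3, 4 and 5.

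Each array was labelled with Cy3 alone. Per the file headers, the authors' files came from Agilent Feature Extraction 9.1.3.1 with a one-colour protocol, which subtracted the background and adjusted for spatial trends, and the deposited values are spot intensity, not scaled between arrays. The headers stand in 6 of the 8 files. The other 2, exposed fish 2 and 3, hold the same columns rounded to 3 significant digits without headers, and their spots were matched to probes by spot number. The optional multiplicative adjustment of the software had changed the signals on the arrays of controls 1 and 6 and exposed fish 2 only. The authors' value table of the series holds the processed intensity of the same arrays, on a linear scale and without centring, with column medians of 17.3 to 39.1. It differed from the scanner files by at most 0.497% for signals of 1 or more, through rounding. The deposited quality columns hold flags of 0 or 1 per spot. In the 6 files with headers each array was on a slide of its own and all were scanned on one day. Slide and scan date are not recorded for the other 2 arrays, so neither was fitted as a batch.

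The processed signal was divided by the array's 75th percentile over the 21495 non-control probes, floored, and taken to log2. Between 14.2% and 22.5% of processed signals per array were below 0 and have no logarithm. The floor, a scaled signal of 0.0332 (log2 of −4.91), is the highest over arrays of the lowest scaled signal among probes well above background. It was set after a first fit had been seen, and other floors were run as alternatives. Values at the floor have no order. The 1080 control spots and all spots marked as non-uniform or population outliers were left out, and saturated spots were kept. Each probe occurs once on the array. Probes were tested when well above background on at least 4 arrays and with at least 2 values per group, which left 14162.

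Exposed and control fish were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment at 5%. Numbers of probes at an unadjusted p under 0.05 with at least a 1.5-fold change are given beside it. Single values were compared with two-sided exact permutation tests over all assignments of the 8 arrays, the smallest p of which is 0.0286. A probe saturated on every array was given no fold. Tested on simulated data with the means and spreads of these 14162 probes over 20 runs of 200 changed probes, the exposed and control comparison recovered 22.2% of 2-fold, 60.7% of 4-fold, 75.5% of 8-fold and 80.5% of 16-fold changes, and 7.04% of its calls were unchanged probes. A run without any changed probe gave 1 call. The simulated spread was drawn separately for each probe, without patterns shared between probes, and values stopped at the floor. Recovery in the real data can therefore differ. Figures were drawn with matplotlib 3.10.9.

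Gene names were taken from the array's own name column. The 6104 sequence accessions in it are GenBank ones, while the fPimPro1.hap1.1 annotation table lists RefSeq accessions only. The 0 matches between them were therefore fixed in advance and do not tell whether these transcripts are annotated. Probes listed by accession or contig stay unnamed. The groups, tests, gene lists and most alternatives were fixed before the data were examined. The rule for named genes took the annotated genes with the 15 largest changes in each direction past the threshold, filled up to 10 per direction by smallest unadjusted p, up to 4 members of each list, and index genes of androgen action in the fish ovary wherever the array names them. As only 14 named probes were measured, all were taken. The 28 lists covered ovarian functions and markers of other cell types, and a list needed 3 measured genes to be tested.

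The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter on dim probes, a filter on all 8 arrays, the authors' value table, a variance trend with robust estimation, array weights, RNA integrity as a covariate, the replicate number as a block, and each array left out in turn. Added after seeing the data were the signal before multiplicative adjustment, scaled floors of 0.02 and 0.1, a floor at a processed signal of 1, leaving out the 2 dimmest arrays, leaving out control 3 and exposed fish 5, and the alpha amylase signal as a covariate.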

Results

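Ovarian gene expression was measured in adult female fathead minnows (Pimephales promelas), a small freshwater fish used in toxicity testing, after 4 days in flowing water with or without 17β-trenbolone. This compound is a synthetic androgen, the active form of a growth promoter used in cattle. RNA from the ovaries of 4 control females, kept in water with the ethanol carrier alone, and of 4 females exposed to a nominal 1 µg/L was hybridised to one-colour Agilent arrays, 1 fish per array. The array carried 21495 probes besides its control spots. The 75th percentile of the processed signal was 374 ± 60.4 (SD, n = 4) on the control arrays and 295 ± 94.8 (SD, n = 4) on the exposed arrays, and the exact permutation test between them gave a two-sided p of 0.229. The share of probes well above background was 66.4% ± 2.78 (SD, n = 4) in controls and 63.2% ± 4.87 (SD, n = 4) in exposed fish, with an exact permutation p of 0.286. The dimmest arrays were those of exposed fish 2, with a 75th percentile of 197, and exposed fish 4, with 230. RNA integrity numbers ranged from 9.4 to 10 and averaged 9.78 in controls and 9.65 in exposed fish. The number of arrays limits the precision of every value that follows.

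The correlation between arrays over the tested probes ranged from 0.948 to 0.974. It averaged 0.954 over the 12 pairs within a group and 0.954 over the 16 pairs between groups, and 16 of the 35 splits of the arrays into 4 and 4 gave a difference at least as large. Without control 3 and exposed fish 5 the means were 0.9538 within and 0.9524 between groups. The real split then gave the largest difference of the 10 splits of the remaining 6 arrays, too few for a share under 0.05. These arrays were left out for being the most alike across groups, which favours a larger difference. The ranking is therefore no separate support for a grouping. Exposed fish 5 had a median correlation of 0.957 with the controls and of 0.954 with the other exposed fish. The highest correlation joined control 3 and exposed fish 5, and the next highest pair reached 0.958. The first principal component held 19.9% of the variance, and its exact permutation p between groups was 0.229.

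**Figure D1:**
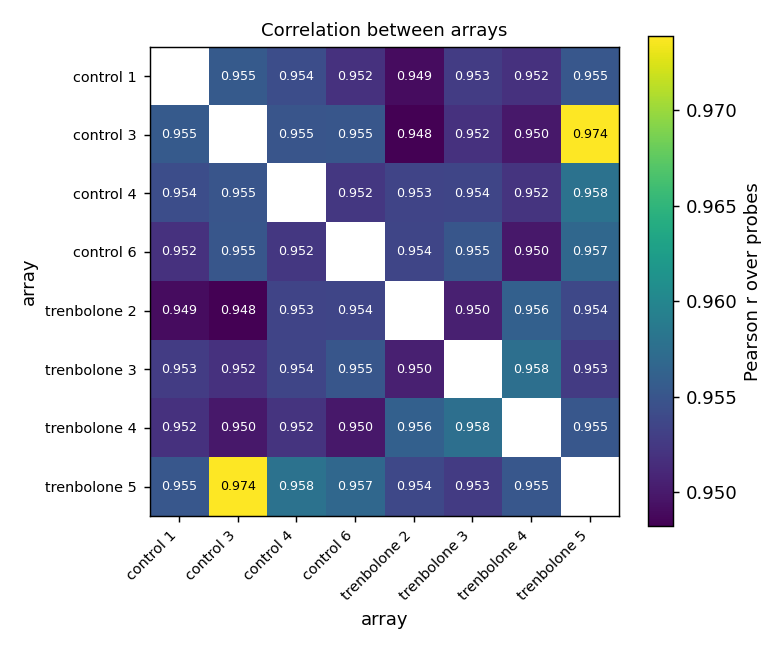
Pearson correlation over the tested probes for each pair of arrays, with controls and exposed fish in the same order on both axes. Control 3 and trenbolone 5 reach 0.974, and no other pair exceeds 0.958.

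The comparison of exposed with control ovaries addressed which transcripts an androgen alters in the female gonad within 4 days. The differences with the smallest p were in probes without a gene name. The signal of probe EA_Pp_63107 was −3.81 ± 0.75 (SD, n = 4) in controls and −0.51 ± 0.50 (SD, n = 4) in exposed fish, on the log2 scale relative to the array's 75th percentile, a 9.85-fold difference with every exposed fish above every control. Probe EA_Pp_70203 read −4.58 ± 0.68 (SD, n = 4) in controls, where 3 of the 4 arrays lay at the floor, and −1.07 ± 0.78 (SD, n = 4) in exposed fish. It was well above background on 3 of the 4 control arrays, so some of the values at the floor were detected signals. The size of its difference depends on the floor, with 3.51 on the log2 scale as given, 2.25 with a higher floor and 3.97 with a floor at a processed signal of 1. In the other direction, EA_Pp_57148 read −3.56 ± 0.28 (SD, n = 4) in controls against −4.65 ± 0.19 (SD, n = 4) in exposed fish, and EA_Pp_59446 read −2.29 ± 0.94 (SD, n = 4) against −4.74 ± 0.34 (SD, n = 4), with 3 of the 4 exposed arrays at the floor. Its difference went from −2.45 to −1.10 with a higher floor and to −3.55 with a floor at a processed signal of 1. These 4 probes have the 2 smallest p in each direction and were chosen after their values were seen. Groups that do not overlap occurred in 495 of all tested probes, or 3.50%, where chance alone gives about 2.86%. With normexp background correction the log2 differences were smaller, at 1.66 for EA_Pp_63107, 1.57 for EA_Pp_70203, −0.044 for EA_Pp_57148 and −0.74 for EA_Pp_59446. None passed the threshold, with limma adjusted p of 0.342 for both probes that were higher and 0.556 for both that were lower. Their 60-base sequences are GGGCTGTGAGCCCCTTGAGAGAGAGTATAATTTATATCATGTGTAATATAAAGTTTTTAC for EA_Pp_63107, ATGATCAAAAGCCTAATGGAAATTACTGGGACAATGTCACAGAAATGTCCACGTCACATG for EA_Pp_70203, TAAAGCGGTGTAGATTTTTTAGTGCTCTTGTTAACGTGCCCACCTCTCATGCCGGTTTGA for EA_Pp_57148 and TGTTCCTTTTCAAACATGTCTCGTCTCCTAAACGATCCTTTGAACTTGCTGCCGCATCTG for EA_Pp_59446. Their positions in the genome were not determined here.

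**Figure D2:**
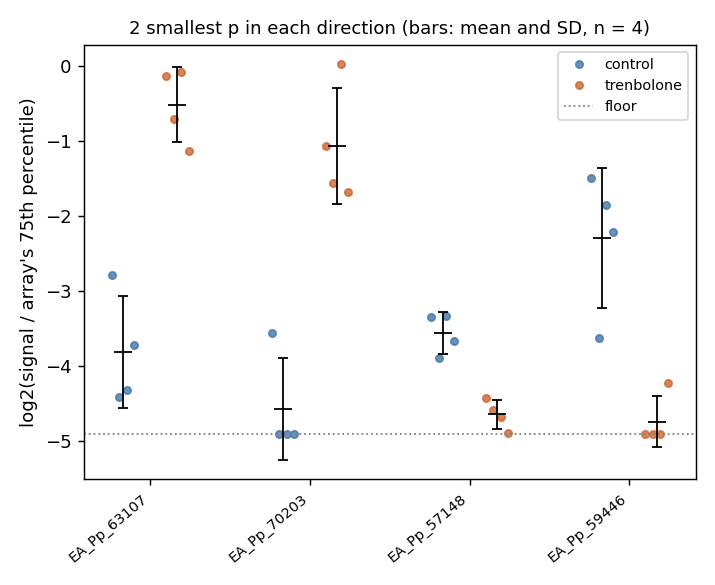
Signal of the probes with the 2 smallest p in each direction, as log2 of the signal over the array's 75th percentile, for each control and exposed ovary, with the mean and SD of 4 arrays per group and the floor as a dotted line. EA_Pp_63107 and EA_Pp_70203 read higher in exposed fish, and EA_Pp_57148 and EA_Pp_59446 read lower.

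Across all probes, limma tested 14162 and found 0 past a false discovery rate of 5%, and the smallest adjusted p was 0.342. At an unadjusted p under 0.05 there were 841 probes, 401 higher and 440 lower in exposed fish, where chance alone gives 708. Of the 35 splits of the arrays into 4 and 4, the real one included, 9 gave at least as many. Splits other than the real one ranged from 335 to 1119, so chance cannot be excluded for this count. With a change of at least 1.5-fold as well there were 633, of which 321 were higher and 312 lower. The share of those that were higher was 50.7%. It was 70.1% with each array's median in place of its 75th percentile and 69.3% after normexp background correction. No direction can therefore be given to the set as a whole. Among the 50 probes with the smallest p, a set chosen by its values, 39 were higher and 11 lower, and none passed 5%. Normexp, quantile normalization, the authors' value table, array weights and a robust variance trend each also gave 0 probes past 5%. Leaving out exposed fish 5 gave 4 probes, and leaving out control 3 gave 1. The labels do not tell which females shared a tank, so the p-values measure the spread between these fish.

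**Figure D3:**
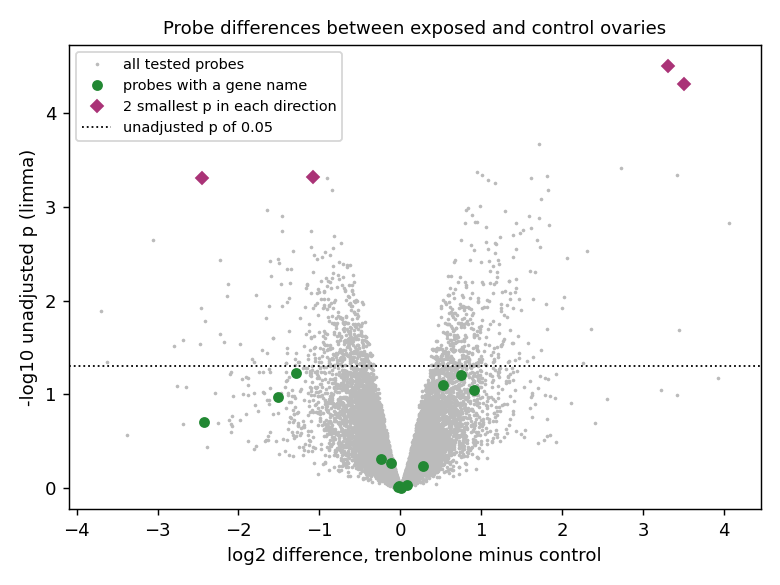
Difference between exposed and control ovaries on the log2 scale against −log10 of the unadjusted limma p for each of the 14162 tested probes, with the named genes and the probes with the 2 smallest p in each direction marked. No named gene lies above the dotted line at an unadjusted p of 0.05.

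Only 34 probes carried a gene name, since most are listed by contig or sequence accession, and 14 of them were measured. The genes of the follicle's activin system were low in both groups. Follistatin, which binds and blocks activin, read −3.61 ± 0.25 (SD, n = 4) in controls and −2.87 ± 0.70 (SD, n = 4) in exposed fish, a 1.67-fold difference with an exact permutation p of 0.114. Inhibin, a gonadal protein that lowers follicle-stimulating hormone, read −3.62 ± 0.64 (SD, n = 4) and −3.34 ± 0.91 (SD, n = 4), with an exact permutation p of 0.629. In both genes the highest exposed fish were 2 and 4, whose arrays were the dimmest, and without them the log2 difference of follistatin went from 0.74 to 0.21 and that of inhibin turned from 0.28 to −0.47. Without exposed fish 5 these differences were 0.99 and 0.64. As both of the dimmest arrays were of exposed fish, brightness and a stronger response in these fish cannot be told apart. Inhibin beta b was not well above background on any array. Neither measured member of this list passed the test adjusted over the list alone, where the smaller p was 0.123, or over all probes.

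Hormone receptors were mostly below detection. Estrogen receptor alpha was well above background on 1 control and 1 exposed array, and estrogen receptor beta and the receptor of follicle-stimulating hormone (FSHR) on 0 of 8. The activin receptor ACTRIIB was well above background on 2 control arrays and 0 exposed arrays, and GnRH-III, a form of gonadotropin-releasing hormone, on 0 and 1. Of the egg envelope genes, zona pellucida glycoprotein 3, a structural protein of the egg coat, was saturated on all 8 arrays, so it has no measurable difference. No probe carried the name of a vitellogenin, an aromatase, another steroidogenic enzyme or the androgen receptor, and these were not assessed here.

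Cyclin B1, which drives entry into cell division and is stored in oocytes, read 4.29 ± 0.15 (SD, n = 4) in controls and 4.18 ± 0.04 (SD, n = 3) in exposed fish, with an exact permutation p of 0.343. Cytochrome b, a mitochondrially encoded part of the respiratory chain, read 1.20 ± 0.39 (SD, n = 4) in controls and 2.11 ± 0.99 (SD, n = 4) in exposed fish, a 1.87-fold difference with an exact permutation p of 0.143. Exposed fish 2 and 4 were again the highest, and exposed fish 5 lay at 0.76, within the controls' range. The log2 difference went from 0.91 to 0.17 without fish 2 and 4 and to 1.35 without fish 5. Lamin B1, a protein of the nuclear lamina, differed by 0.53 on the log2 scale, with an exact permutation p of 0.0857, and by 0.28 without control 1 and 0.65 without control 6.

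Pentraxin, an acute-phase protein of innate immunity, read −1.09 ± 1.28 (SD, n = 4) in controls and −2.38 ± 0.45 (SD, n = 4) in exposed fish, with an exact permutation p of 0.0857. It had the smallest limma p of the named genes, 0.0591 before adjustment and 0.826 adjusted over all probes. Complement C3S, a plasma protein made mainly in the liver, read −2.63 ± 1.73 (SD, n = 4) and −4.14 ± 0.86 (SD, n = 4), with an exact permutation p of 0.143. Control 1 was the highest fish for both genes, at 0.59 for pentraxin and −0.53 for complement C3S. The difference of −1.29 for pentraxin went to −0.73 without control 1 and −1.71 without control 3, and that of −1.51 for complement C3S to −0.81 and −2.18. With the replicate block, where only fish 3 and 4 of each group carry the comparison, the differences were −0.58 and −0.51. Complement C3S was well above background on only 2 of the 4 exposed arrays, and its difference was −0.34 with normexp, −0.96 with the higher floor and −2.18 with a floor at a processed signal of 1. The leukocyte integrin chain CD 18 type 2 differed by −0.23, with an exact permutation p of 0.543, and turned to 0.04 with the replicate block.

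Alpha amylase, a digestive enzyme of the exocrine pancreas, had the widest spread of the named genes. It read 0.86 ± 3.36 (SD, n = 4) in controls and −1.57 ± 2.25 (SD, n = 4) in exposed fish, with an exact permutation p of 0.229. It was high in control 1 at 2.12, control 3 at 2.60 and control 4 at 2.87, and low in control 6 at −4.17. Among exposed fish it was −3.78 in fish 2, 0.99 in fish 3, −3.11 in fish 4 and −0.37 in fish 5. Exposed fish 2 and 4 had low amylase with high cytochrome b and follistatin, whereas control 6 had low amylase with cytochrome b at 1.42 and follistatin at −3.55, within the range of the other controls. The difference of −2.43 between the group means was −4.10 without control 6 and −0.55 without exposed fish 2 and 4. Without control 6 the limma p was 0.0065 before adjustment and 0.807 adjusted over all probes. Adenosine deaminase, cadherin 17, taurine transporter and myoblast determination protein differed by 0.08, 0.0043, −0.02 and −0.03 on the log2 scale, each less than the spread between fish.

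**Figure D4:**
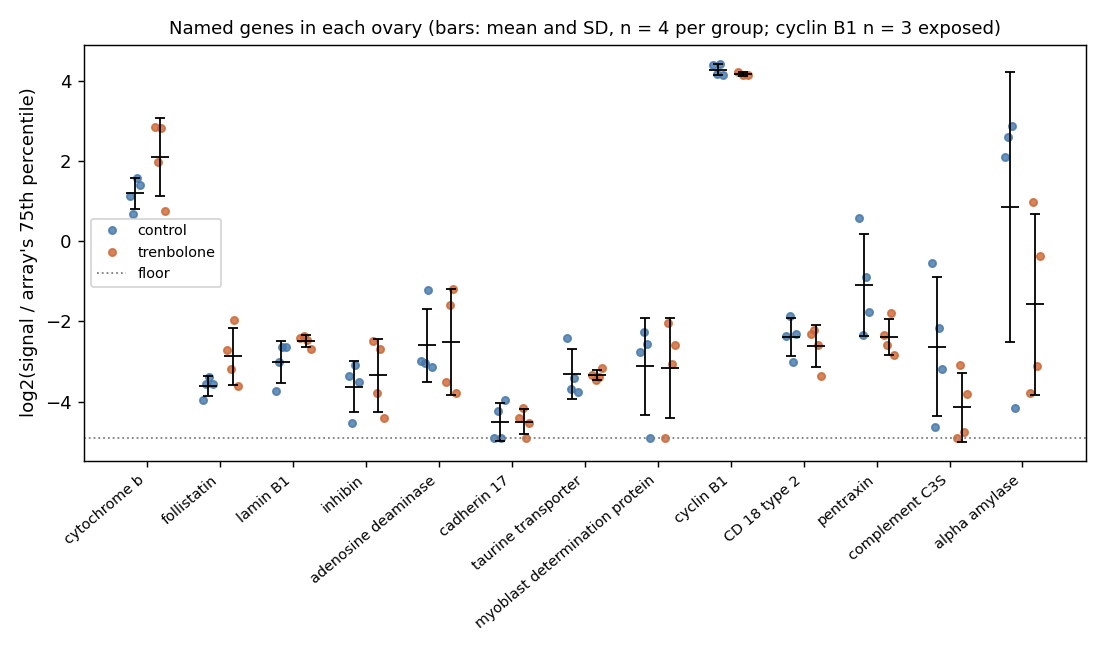
Signal of the named genes measured without saturation, as log2 of the signal over the array's 75th percentile, for each control and exposed ovary, with the mean and SD of each group and the floor as a dotted line. The groups overlap for every gene plotted, and alpha amylase spans from −4.17 to 2.87 among controls alone.

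Of the 13 named genes with a measurable difference, 6 were higher and 7 lower in exposed fish. With all 8 arrays, 0 had an unadjusted limma p under 0.05, and the smallest p adjusted over these genes alone was 0.277. With single arrays left out, the smallest unadjusted limma p was 0.0033, for cytochrome b without exposed fish 5. Its p adjusted over all probes was then 0.440. Of the 28 gene lists, 6 had a measured gene and none had 3, the minimum for a test, so no list was tested.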

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

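The tests of explanations for the amylase spread were chosen after the result was seen. The splits of the arrays were planned for the count past 5% only, and their use for unadjusted counts was added later. In 39 groups of 4 values checked for a sample far from the others, 4 were found, and chance alone gives about 1.95 where no values are floored. Alpha amylase read −4.17 in control 6, where the nearest other control read 2.12. Adenosine deaminase read −1.23 in control 4, against −2.99 in the nearest other control. EA_Pp_70203 read −3.56 in control 1 while the other controls lay at the floor of −4.91. EA_Pp_59446 read −4.24 in exposed fish 5 while the other exposed fish lay at the floor. Groups whose other values all lie at the floor are flagged by construction, as for both of these probes. The count of 4 therefore cannot be set against 1.95.

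The alpha amylase signal differed up to 131-fold between single ovaries. A defect of that spot is argued against by 15 other probes that followed its profile over the arrays (r above 0.9 and a range of at least 3 on the log2 scale), where the highest of 100 permuted array orders gave 10. The exposure stays open: the range of 7.04 (log2) among controls exceeds the difference of 2.43 between the group means, with exposed fish lower, but it rests on control 6 alone, and the other controls span 0.75. A candidate explanation is pancreatic tissue collected with some ovaries, for which the same 15 probes are what is needed, although a set of genes regulated together within the ovary would give them too. Amylase is the only member of the pancreas list that the array names, and none of the 15 probes has a name, so other pancreatic transcripts could not be looked up.

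The number of probes past a false discovery rate of 5% was 0, a count that all 35 splits of the arrays reach by construction, so the splits decide nothing there. Of the 35, 11 gave at least 1 probe, the real split not among them, and the highest other split gave 5. For an unadjusted p under 0.05 with at least a 1.5-fold change the count was 633, reached in 10 of the 35 splits, with 859 in the highest other split. Chance cannot be excluded for that count.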

How the results depend on the processing

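The count of probes past 5% was 0 under every alternative except leave-one-out runs, where it ranged from 0 to 4, with 1 probe without control 3 and 4 without exposed fish 5. None of these probes has a gene name or is among the 4 printed, and without both fish the count was 0. Of the 4 probes without exposed fish 5, 1 was well above background on all arrays. The 1 probe without control 3 was not. The smallest adjusted p over all alternatives was 0.015, and with a floor at a processed signal of 1 it was 0.0596. The unadjusted count of 633 became 274 with normexp and 322 with the higher floor. The cause was not tested for normexp, while the higher floor removes differences among dim probes by construction. It ranged from 512 to 857 when single arrays were left out and stayed within 1.5 times of 633 in all other runs. The labels share 2 replicate numbers between groups, and the deviations of same-numbered fish correlated at −0.10 and 0.04, so no pairing was seen. With 2 shared numbers and no tank labels, a pairing of small effect cannot be excluded. The replicate block rests on fish 3 and 4 of each group alone, since every other number occurs in a single fish. With it the adjusted count was 0 and the unadjusted count 765. Slide or scan date as a block was not run, since the 6 arrays with a recorded slide each had their own and the other 2 have none recorded. The floors, the signal before multiplicative adjustment, the 2 dimmest arrays left out, control 3 and exposed fish 5 left out together, and the amylase covariate were chosen after seeing the data. Cytochrome b, follistatin, lamin B1, pentraxin, complement C3S, cyclin B1 and alpha amylase kept their direction, though not their size, in every alternative that gave a value. The log2 differences ranged from 0.17 to 1.35 for cytochrome b, 0.21 to 1.01 for follistatin, 0.28 to 0.65 for lamin B1, −1.71 to −0.58 for pentraxin, −2.29 to −0.34 for complement C3S and −4.10 to −0.55 for alpha amylase, and the values nearest 0 for cytochrome b, follistatin and alpha amylase came without the 2 dimmest arrays. Both of the dimmest arrays were of exposed fish, so brightness and a stronger response in these fish cannot be told apart. The direction was not kept by adenosine deaminase, cadherin 17, inhibin, taurine transporter, myoblast determination protein and CD 18 type 2. No named gene passed 5% in any of them. Without the filter, lists of 3 genes could be tested for hormone receptors (camera p = 0.538, and p = 0.557 with an estimated correlation) and follicle growth factors (p = 0.163, and p = 0.229), although 2 and 1 of their genes were at the floor on all arrays. Signal over background limits what can be said of the receptors.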

Other observations

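All tests in this part were chosen after the result was seen. A set of 29 probes, none with a gene name, was not well above background in at least 2 ovaries and at or above the array's 75th percentile in at least 2 others. Only 2 of them separated exposed from control fish fully, and 9 of the 35 splits of the arrays separated as many. Over all tested probes the share that separated fully was 3.50%. The exposure does not account for the set as a whole by this measure. An effect on part of the probes, or in part of the fish, could not be excluded by it. Over these probes control 3 and exposed fish 5 correlated at 0.62, the highest of the 28 pairs. In 1000 permutations within probes the highest pair reached this in a share of 0.01, and 0.76 at most. Separate spot defects would thus seldom give such a likeness. These arrays were also the most alike over all tested probes, so this is not separate evidence of their likeness. The next highest pair reached 0.28, below the permuted median of 0.38, so spot defects stay open for the other arrays. Differences in gene sequence or in expression between individual fish stay open too, and no other biological explanation was tested.

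Control 3 and exposed fish 5 were more alike than any other pair of ovaries. Over the 1131 probes with an SD of at least 1 on the log2 scale, their deviations from the probe mean correlated at 0.44, and the next highest of the 28 pairs reached 0.05. Like brightness is argued against by the 3 other pairs at least as alike in brightness, where the highest correlation was −0.026. The same RNA on both arrays is argued against by 15 probes that follow alpha amylase on the other 6 arrays, chosen without these arrays. All 15 were higher in control 3, by a median of 2.95 on the log2 scale. No spike-in spot lay more than 0.46 from the median difference of the spike-in spots, a centring not applied to the 15 probes. Another test, on the 78 bright probes that differed at least 4-fold, decided nothing, since the 119 spike-in spots allow up to 171. Part of one sample's RNA mixed into the other stays open, since 4 probes were bright in control 3 and not well above background in exposed fish 5 and 1 the other way, too few to decide. The labels give no parentage, tank or spawning state, so no biological explanation was tested.

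Among the probes with "minus" in their name, 1618 had a partner of the same name without it, and only these were counted. Of these 1618, 599 were well above background on at least 4 arrays, against 864 of the partners. In 294 pairs the "minus" probe was detected alone, in 559 the partner alone, in 305 both and in 460 neither.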
